A study of Homo sapiens with 12 samples.

How the data were processed

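Polyadenylated RNA was measured by sequencing in 12 libraries of human breast cancer cell lines, in 6 groups of 2 libraries each. The groups combined 3 lines (MCF7, WS8 and TAMR) with vehicle or 4-hydroxytamoxifen (4-OHT), per the labels. Group and replicate of every library were taken from the labels. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

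The deposited gene table held estimated (expected) counts for 20527 gene symbols, not whole numbers and not normalized. Library totals equalled those of the deposited transcript table, which held estimated counts for 94459 transcripts and served only for that comparison. The deposited normalized gene table held values on a log2 scale. They were checked to equal log2 of the estimated count divided by a factor of its own for each gene and library, plus 1. Over 8601 genes with more than 200 counts in every library, the geometric mean of a gene's factors lay within 1.9e-14 of 1, and no cell was 0 in one table only. These values were therefore used as they were in the limma alternative, where the plan had assumed a scale that still needed a logarithm. The deposited normalized transcript table was not used here. The submitters' processing notes name DESeq2 and the hg19 build, without a version or role. The aligner, the quantifier, the annotation and any filter are not given in the sources used here.

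The estimated counts were rounded to whole numbers and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3). TMM factors scaled the libraries, filterByExpr left 14072 genes, and Benjamini-Hochberg adjusted p under 0.05 was the threshold for a call. All 12 libraries entered 1 fit with a coefficient per group, which left 6 residual degrees of freedom. The common biological coefficient of variation was 0.19. Levels are CPM with TMM-scaled library sizes, given as mean ± SD over the 2 libraries of a group. SE is an approximate standard error, the absolute fitted log2 fold change divided by the square root of the quasi-likelihood F. For genes near 0 counts in a group it can understate how far the change moves when a library is left out. The fitted values used edgeR's default prior count of 0.125. Library totals ran from 19705404 to 28573165 counts, so that 3 counts in a library corresponded to 0.102 to 0.152 CPM. Against a group at 0 counts, a fold is given as a lower bound, computed with 3 counts over the group. Against a group with 1 to 3 counts it is a ratio with its 95% counting interval. Bounds and intervals cover counting error only, and reads without molecular identifiers are not independent molecules.

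Comparisons were TAMR against each other line and WS8 against MCF7 in vehicle, TAMR against each other line in 4-OHT, 4-OHT against vehicle in each line, and the differences between lines in that response. Genes called in the same direction against both MCF7 and WS8 in vehicle formed a further set. Since both of these tests used the same TAMR libraries, 20 simulations of unchanged groups gave the correlation that sharing alone produces when no gene differs. They cannot give a chance overlap of calls, since unchanged groups yield almost no calls.

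The comparisons, the tests, 18 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, with camera's estimated correlation and with fry, each adjusted over the 18 lists of a comparison. Counts of list members are given over all genes tested and adjusted over the list alone. Named genes are the 6 with the largest positive and the 6 with the largest negative log2 fold change among called genes of average log2 CPM at least 2 whose 2 groups did not overlap. For interactions the last condition was dropped, and for the set against both lines the smaller of the 2 changes ranked the genes. The first 2 to 4 called members of each list and 8 genes of interest (GRHL2, FOXA1, ESR1, AGR2, LYPD3, TFF1, PGR and GREB1) were added. The series title names GRHL2 and FOXA1, and AGR2 and LYPD3 come from general knowledge of the study, which may have picked them from these libraries.

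The procedure was tested on simulated data drawn from the real means and library sizes, with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. For 4-OHT against vehicle in MCF7 it recovered 63 and 81 of them among 13886 genes, with 7 false calls in 151. For TAMR against MCF7 in vehicle it recovered 61 and 81 among 13891 genes, with 7 false calls in 149. For 4-OHT against vehicle in TAMR it recovered 64 and 90 among 13897 genes, with 9 false calls in 163. For the response of TAMR minus that of MCF7 it recovered 32 and 70 among 13887 genes, with 8 false calls in 110. In the camera test, a raised list of 30 genes was called, and 7 of 200 random lists had an unadjusted p under 0.05. The genes were simulated independently of each other, so this cannot show how camera behaves for lists whose members vary together.

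Alternatives were upper-quartile and RLE scaling, DESeq2 1.42.0, limma-trend on the deposited log2 values, no filter on low counts, at least 1 CPM in at least 4 libraries, the replicate number as a block (shared or within each line), only the groups compared, a stricter threshold, a 2-fold minimum and leaving out each library in turn. A leave-one-out fit leaves 1 library in a group, which is then assumed to vary like the other groups. A fit without 3 libraries that stood apart from their replicates, and a fit with the per-gene factors of the deposited normalized table as offsets, were added after seeing the data. Without the 3 libraries MCF7 vehicle, MCF7 4-OHT and WS8 vehicle hold 1 library each, so their spread is likewise taken from the other groups. The reference at hand was GRCh38.p14, not the build in the submitters' notes, so it was used only for which genes neighbour each other, and no coordinates are given.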

Results

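RNA was sequenced from 3 human breast cancer cell lines. MCF7 is an oestrogen receptor-positive line, WS8 an MCF7 derivative sensitive to 4-OHT, and TAMR an MCF7 derivative resistant to it, per the labels. 4-OHT is the active metabolite of the anti-oestrogen tamoxifen. Each line received vehicle or 4-OHT for 24 h in hormone-free medium, with 2 libraries per group and 12 libraries in all. The labels give 2 days in that medium before treatment, whereas the series text gives 24 h. Library totals ran from 19705404 counts (WS8 4-OHT replicate 1) to 28573165 (TAMR 4-OHT replicate 2). The first principal component held 56.2% of the variance and separated the 4 TAMR libraries from the other 8, and the second held 21.6% and separated WS8 from MCF7. Counts of the replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom between 5.96 and 59.6. Adjusted p-values are those of edgeR's quasi-likelihood test for genes and of limma's camera for gene lists.

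A set of 3 libraries stood apart from their replicates. MCF7 4-OHT replicate 2 had 16779 genes with a count, against 15118 to 15789 in the other libraries, and 636 genes stood above 1 CPM there and over 5 times their level in any other library. These genes included 17 of 18 melanocyte-lineage genes, such as PMEL, a melanosome protein, at 829 CPM against 3.92 in replicate 1. In MCF7 vehicle replicate 2, 29 WS8-specific genes stood at a median of 0.26 of their WS8 level above their share in replicate 1. WS8-specific here means high in WS8 with 4-OHT and low in MCF7 4-OHT replicate 1, whatever the level in TAMR. For WS8 vehicle replicate 1, 41 genes were chosen as high in TAMR and near absent from WS8 with 4-OHT, whatever their MCF7 level. They stood there at a median of 0.059 of their TAMR level, against 0.00071 in replicate 2. Chosen likewise, 3 genes high in replicate 1 of both MCF7 groups, whatever their TAMR level, stood at 0.11 of their MCF7 level, against 0.006. The basal keratin KRT5 stood at 6.21 CPM against 0, and at 0 in both TAMR vehicle libraries.

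TAMR was compared with MCF7 in vehicle to ask how the resistant line differs from its parent without drug, with GRHL2 and FOXA1, transcription factors of the luminal lineage, in the title of the series. GRHL2 was 1.78-fold higher in TAMR (301 ± 16 CPM against 169 ± 31, SD, n = 2 per group, adjusted p = 0.0029), while FOXA1 stood at 356 ± 14 against 355 ± 64 CPM (adjusted p = 0.98). Among genes induced by oestrogen in breast cancer cells, TFF1, a secreted trefoil peptide, was 9.43-fold higher (506 ± 82 against 53.6 ± 0.64 CPM, adjusted p = 5.1e-06). By contrast GREB1, an oestrogen receptor cofactor, was 7.63-fold lower (18.6 ± 7.9 against 142 ± 34 CPM, adjusted p = 0.00015). PGR, the progesterone receptor, had 0 counts in both TAMR libraries and 9.63 ± 3 CPM in MCF7, at least 176-fold lower (adjusted p = 2e-04). AGR2, a protein disulfide isomerase of secretory cells, was 8.52-fold higher (121 ± 35 against 14.2 ± 11 CPM, adjusted p = 0.00083), and the surface protein gene LYPD3 2.36-fold higher (126 ± 15 against 53.5 ± 6.4 CPM, adjusted p = 0.00011). The log2 fold change of AGR2 was 3.09, with 2.44 without MCF7 vehicle replicate 1 and 4.32 without replicate 2. ESR1, the oestrogen receptor gene, was 1.32-fold lower (309 ± 31 against 407 ± 28 CPM, adjusted p = 0.04). That call ended without MCF7 vehicle replicate 1 (0.069), MCF7 vehicle replicate 2 (0.18), TAMR vehicle replicate 1 (0.065) or TAMR vehicle replicate 2 (0.22). It also ended without the 3 libraries above, without a filter on low counts, and with the deposited per-gene factors as offsets.

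**Figure D1:**
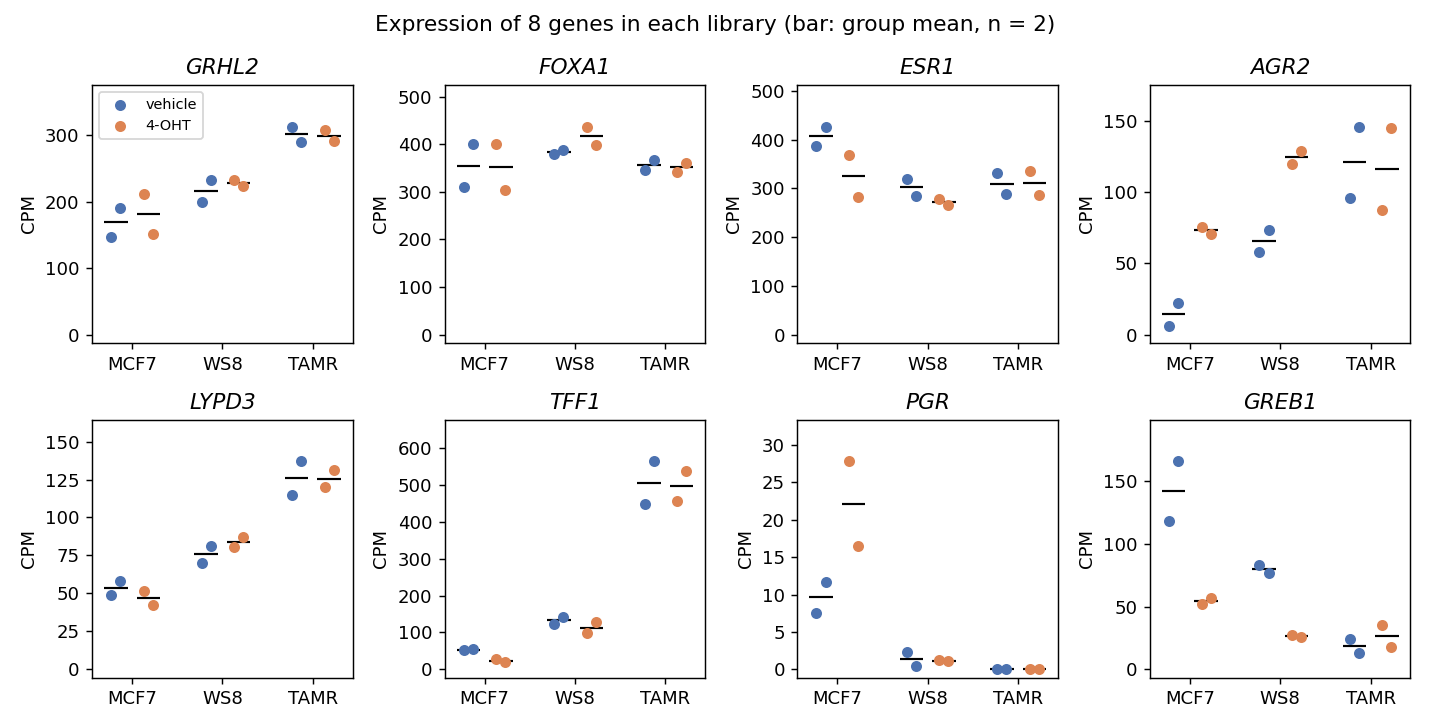
Expression of 8 genes of interest in CPM (linear axes) in each of the 12 libraries, by line, with vehicle and 4-OHT in different colours and a bar at each group's mean (n = 2). TFF1 stands at 506 and 497 CPM in TAMR with vehicle and 4-OHT, while PGR is at or near 0 there.

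Across all genes, 3486 were higher and 3672 lower in TAMR than in MCF7 in vehicle, of which 1582 and 1512 changed at least 2-fold. Many of the largest differences were in genes near absent from one line. TNFSF15, a cytokine of the tumour necrosis factor family, stood at 475 ± 43 CPM in TAMR and 3 counts in both MCF7 libraries together, a ratio of 7570 (95% counting interval 2590 to 36700). The endoderm transcription factor genes FOXA2 (18.9 ± 0.91 CPM) and GATA4 (11.2 ± 0.52 CPM) had 0 counts in MCF7 in vehicle, at least 300-fold and at least 178-fold higher in TAMR (adjusted p = 5.6e-05 and 5.8e-05). In the other direction, PRKAR2A, a regulatory subunit of protein kinase A (124 ± 20 CPM in MCF7), MBD2, a reader of methylated DNA (71.7 ± 5.4 CPM), RAB27B, a GTPase of vesicle secretion (68.4 ± 14 CPM), and OXCT1, an enzyme of ketone body use (64.3 ± 16 CPM), had 0 counts in TAMR. They were at least 2240-, 1300-, 1240- and 1160-fold lower. C5orf42 (at least 925-fold) and PCDHGB5 (at least 843-fold) completed the 6. PCDHGB5 lies in a cluster of protocadherin genes that share exons, so its count is uncertain. TNC and VCAN, genes of matrix proteins, and FOXN4 completed the highest 6. TNC was 765-fold higher (log2 9.58, with 8.67 without MCF7 vehicle replicate 1 and 13.72 without replicate 2), and FOXN4 had a ratio of 841 (interval 151 to 33200). VCAN was at least 409-fold higher (adjusted p = 0.017), and its call ended without MCF7 vehicle replicate 1 (0.075), MCF7 vehicle replicate 2 (0.074) or TAMR vehicle replicate 1 (0.059). The fitted log2 fold changes behind the ratios also moved over 1.5 times. TNFSF15 went from 12.77 to 11.87 and 16.52 without MCF7 vehicle replicates 1 and 2, and FOXN4 from 9.38 to 11.75 and 8.48 without these and 8.61 without TAMR vehicle replicate 2. Of 83 called named genes, 74 kept their call whichever library was left out.

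Of the 18 gene lists, cell cycle and DNA replication genes were higher in TAMR than in MCF7 in vehicle, with 38 of 44 called higher and 0 lower (median log2 fold change 1.04, camera adjusted p = 4.6e-11, and adjusted p = 0.81 with an estimated correlation). Adjusted over the list alone, 38 were also higher. RRM1, a subunit of ribonucleotide reductase, was 3.09-fold higher (185 ± 18 against 59.9 ± 14 CPM) and TOP2A, a topoisomerase of dividing cells, 2.92-fold (525 ± 74 against 180 ± 42 CPM). Cytosolic ribosomal protein genes were lower, with 30 of 40 called lower and 1 higher over all genes and adjusted over the list alone (median −0.46, adjusted p = 2.6e-07, and adjusted p = 0.81 with an estimated correlation). RPS6 was 1.88-fold lower (784 ± 10 against 1470 ± 43 CPM), and since ribosomal genes have many processed pseudogenes, their counts are uncertain. The other 16 lists were not called as sets (adjusted p of 0.071 or more).

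Many members of these lists changed in both directions. Luminal transcription factors had 10 of 22 members higher and 7 lower (median 0.3). Among them XBP1, a secretory and stress response factor, was 11.6-fold higher (2410 ± 95 against 208 ± 3.9 CPM, adjusted p = 9.1e-08) and the epithelial factor ELF3 4.62-fold. The AGR2 and LYPD3 family list had 4 higher and 3 lower of 9 (median 0.33), with CD59, a complement inhibitor, 2.13-fold lower. Oestrogen-induced genes had 16 higher and 11 lower of 38 (median 0.29). The secreted trefoil peptide gene TFF3 was 54.8-fold higher (367 ± 75 against 6.68 ± 1.7 CPM) and CCND1, cyclin D1, 2.03-fold. Basal and squamous keratinocyte genes had 8 higher and 3 lower of 21 (median 0.79). EGFR, a growth factor receptor, was 18.1-fold higher (174 ± 47 against 9.58 ± 1.5 CPM) and the keratin gene KRT15 115-fold (369 ± 120 against 3.19 ± 1.9 CPM, log2 6.84, and 7.62 without MCF7 vehicle replicate 2). Receptor tyrosine kinases and ligands had 10 higher and 4 lower of 25 (median −0.2), with the growth factor IGF2 44.2-fold higher (41.9 ± 4.6 against 0.939 ± 0.22 CPM). Epithelial junction genes had 8 higher and 6 lower of 28 (median 0.02), with KRT19 3.29-fold higher and EPCAM 2.38-fold lower, and mesenchymal genes had 3 higher and 5 lower of 20 (median 0.31). Cholesterol genes had 7 higher and 5 lower of 24 (median 0.14), unfolded protein response genes 6 higher and 8 lower of 25 (median −0.17), and markers of non-epithelial cells 1 higher and 2 lower of 6 (median 1.56). Hypoxia and glycolysis genes had 10 higher and 3 lower of 21 (median 0.31), with the glucose transporter SLC2A1 3.02-fold higher and the glycolytic enzyme ENO1 4.21-fold lower. Apoptosis regulators had 10 higher and 4 lower of 22 (median 0.39), with BCL2, an inhibitor of apoptosis, 18.5-fold lower (7.49 ± 2.7 against 138 ± 14 CPM, adjusted p = 1e-05).

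MAPK output genes had 1 higher and 6 lower of 19 (median −0.8), including EPHA4, an ephrin receptor, 10.5-fold lower (16.3 ± 2.6 against 171 ± 1.2 CPM). Antigen presentation genes had 2 higher and 1 lower of 17 (median −0.31), and type I interferon response genes 1 higher and 17 lower of 36 (median −1.72, adjusted p = 0.071). IFI6, an interferon-induced gene, stood at 6.7 ± 1.3 against 135 ± 130 CPM. Its log2 fold change of −4.33 was −5.06 without MCF7 vehicle replicate 1 and −2.78 without replicate 2, the library with WS8-specific genes. Mitochondrially encoded genes had 5 lower and 0 higher of 13 (median −0.51, adjusted p = 0.071). Which of these lists passed depended on the libraries, as the interferon list was called without MCF7 vehicle replicate 1 (4.9e-09) and not without replicate 2 (0.44), and the mitochondrially encoded list without MCF7 vehicle replicate 2 (0.00018) or TAMR vehicle replicate 2 (0.0014) and not without MCF7 vehicle replicate 1 (0.52). The cholesterol list was called without MCF7 vehicle replicate 1 (0.018). The calls of the 4 named ones (MT-ND3, MT-ND2, MT-ND4L and MT-CO1) ended without MCF7 vehicle replicate 1 (adjusted p of 0.088, 0.31, 0.36 and 0.28) or TAMR vehicle replicate 1 (0.088, 0.23, 0.22 and 0.25). Adjusted over the list alone, the counts of the 16 uncalled lists were unchanged except for MAPK output (1 higher, 5 lower), markers of non-epithelial cells (2 and 2) and mitochondrially encoded genes (0 and 1). Median, mean and test differed in sign for the mesenchymal, receptor tyrosine kinase and antigen presentation lists.

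TAMR was compared with WS8 in vehicle to set the resistant line against a sensitive line of the same origin. LYPD3 was 1.67-fold higher in TAMR (126 ± 15 against 75.7 ± 8 CPM, adjusted p = 0.0023) and TFF1 3.82-fold (506 ± 82 against 132 ± 15 CPM, adjusted p = 7.9e-05). GREB1 was 4.32-fold lower (18.6 ± 7.9 against 80.2 ± 4.2 CPM, adjusted p = 0.00095), and PGR, at 1.4 ± 1.4 CPM in WS8, was at least 23.7-fold lower (adjusted p = 0.0024). The fitted log2 fold change of PGR was −8.1, with −6.49 without WS8 vehicle replicate 1 and −8.85 without replicate 2. GRHL2 was 1.39-fold higher (301 ± 16 against 217 ± 23 CPM, adjusted p = 0.041). The call ended without TAMR vehicle replicate 1 (0.17), TAMR vehicle replicate 2 (0.12), WS8 vehicle replicate 1 (0.26) or WS8 vehicle replicate 2 (0.073). AGR2 (121 ± 35 against 65.7 ± 11 CPM, adjusted p = 0.14), FOXA1 (356 ± 14 against 384 ± 5.9 CPM; 0.57) and ESR1 (309 ± 31 against 303 ± 25 CPM; 0.88) did not pass the test. In all, 3364 genes were higher and 3316 lower in TAMR, 1350 in each direction by at least 2-fold.

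Interferon genes separated TAMR most clearly from WS8 in vehicle. Of 36 type I interferon response genes, 32 were lower in TAMR and 0 higher, over all genes and adjusted over the list alone (median −4.03, adjusted p = 5.4e-11, and adjusted p = 0.92 with an estimated correlation). The interferon signalling factors STAT1 and IRF9 were 6.78-fold (127 ± 2.1 against 860 ± 38 CPM) and 9.99-fold lower (8.72 ± 2.1 against 87.2 ± 13 CPM), and IFI6 was 109-fold lower (6.7 ± 1.3 against 733 ± 110 CPM). Antigen presentation genes had 11 of 17 lower and 1 higher (12 and 1 adjusted over the list alone, median −1.49, adjusted p = 0.012, and adjusted p = 0.92 with an estimated correlation). B2M, the light chain of class I molecules, was 2.11-fold lower (136 ± 5.7 against 287 ± 6.5 CPM). HLA-A was 5.1-fold lower and belongs to a family whose members share reads, so its count is uncertain. Cell cycle genes had 23 of 44 higher and 0 lower in both counts (median 0.62, adjusted p = 0.00013, and adjusted p = 0.92 with an estimated correlation). The replication helicase gene MCM5 was 2.99-fold higher and the cell cycle factor E2F1 2.61-fold. The other 15 lists were not called (adjusted p of 0.052 or more). Luminal factors (0.052) were called whichever library was left out, and hypoxia genes (0.1) without some libraries, in fits with 1 library in a group. Luminal factors had 10 higher and 2 lower of 22, with XBP1 5.64-fold higher, and MAPK output genes had 2 higher and 9 lower of 19, with EPHA4 12.5-fold lower. Adjusted over the list alone, these 2 lists gave the same counts. Median, mean and test differed in sign for the AGR2 and LYPD3 family, epithelial junction and basal lists. WS8 vehicle replicate 1 entered this comparison, with the 41 genes high in TAMR at a median of 0.059 of their TAMR level. This did not hold for each such gene, as TNFSF15 stood at 0.268 CPM there and 0.257 in replicate 2.

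Genes that differed from both sensitive lines in vehicle in the same direction formed a shared set. TNFSF15, FOXA2, GATA4, TNC, FOXN4 and KRT13, a keratin of stratified squamous epithelium, were the highest, and PRKAR2A, MBD2, RAB27B, PCDHGB5, POLI and OXCT1 the lowest. KRT13 stood at 78.4 ± 13 CPM in TAMR, 365-fold above MCF7 (0.206 ± 0.17 CPM) and 161-fold above WS8 (0.476 ± 0.1 CPM), with adjusted p of 3e-07 and 3.2e-07. Its log2 fold change against MCF7 of 8.51 was 7.90 without MCF7 vehicle replicate 1 and 9.73 without replicate 2. TNFSF15 was 1780-fold above WS8, and TNC 297-fold (log2 8.21, with 13.72 without WS8 vehicle replicate 1, and 7.11 without replicate 2, where its call ended at adjusted p = 0.059). Against WS8, the ratios of GATA4 and FOXN4 were 558 (interval 99.7 to 22100) and 877 (157 to 34700), and that of FOXA2 469 (130 to 3880). The fitted log2 fold change of GATA4 went from 8.8 to 11.12 and 7.83 without WS8 vehicle replicates 1 and 2, and that of FOXN4 to 11.75 and 8.46, and to 8.64 without TAMR vehicle replicate 2. RAB27B was at least 2480-fold, PRKAR2A at least 1330-fold and MBD2 at least 1320-fold lower than in WS8. POLI, a translesion DNA polymerase, was at least 793-fold lower than in MCF7 and at least 567-fold lower than in WS8. In all, 2328 genes were higher and 2341 lower than in both lines, 941 and 908 of them by at least 2-fold in each, and 90 were called in opposite directions. Independent lists of these sizes would share 833 and 865. Across genes, the 2 log2 fold changes correlated at r = 0.843 with a covariance of 2.37, against 0.496 and 0.117 in simulated unchanged groups that share the TAMR libraries. Those groups held no effects, so their 0 genes called in both was fixed in advance and is no chance value for the shared calls. Independent lists do not allow for the shared libraries either. The covariance exceeded the simulated one by 2.25, and genes are not independent replicates.

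Several of the genes lowest in TAMR were neighbours. A set of 35 autosomal genes stood above 2 CPM in each of the 8 MCF7 and WS8 libraries and had at most 3 counts in each TAMR library. In the gene order of GRCh38.p14, 7 of them formed an unbroken run of expressed genes on chromosome 18: ME2, SMAD4, MEX3C, MBD2, POLI, C18orf54 and RAB27B. SMAD4, the shared mediator of TGF-beta signalling, averaged 35.2 CPM over the 8 MCF7 and WS8 libraries, MEX3C 41.3, MBD2 67.1 and RAB27B 90.4 CPM, and no gene of the run had more than 1 count in a TAMR library. The expressed genes next to the run, SKA1 and TXNL1, averaged 5.81 and 1.56 times their MCF7 and WS8 level in TAMR. This run was noticed after the values were seen.

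**Figure D2:**
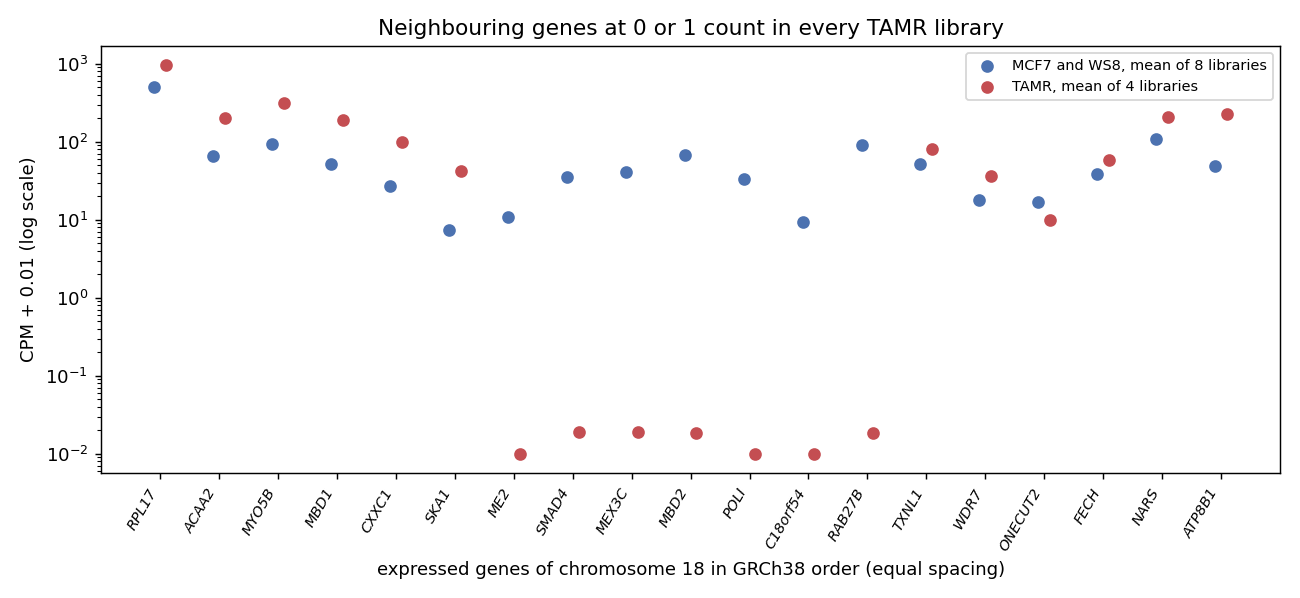
Mean CPM plus 0.01 (log scale) of 7 neighbouring chromosome 18 genes and 6 expressed genes on each side, in GRCh38 order with equal spacing, for TAMR (4 libraries) and for MCF7 with WS8 (8 libraries). The genes from ME2 to RAB27B average 9.43 to 90.4 CPM in MCF7 and WS8 and lie at or near 0 in TAMR, while the flanking genes are expressed in both.

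WS8 was compared with MCF7 in vehicle as the reference for how far sensitive lines of this origin differ. Interferon genes were higher in WS8, with 25 of 36 called higher and 0 lower (30 and 0 adjusted over the list alone, median 2.32, adjusted p = 3.1e-17, and adjusted p = 0.58 with an estimated correlation). STAT1 was 3.46-fold higher (860 ± 38 against 248 ± 120 CPM, adjusted p = 0.0024) and IRF9 3.08-fold (87.2 ± 13 against 28.3 ± 9.2 CPM, adjusted p = 0.0023). Antigen presentation genes had 9 of 17 higher and 0 lower (10 adjusted over the list alone, median 1.75, adjusted p = 1.8e-05, and adjusted p = 0.58 with an estimated correlation). B2M was 1.7-fold higher. MCF7 vehicle replicate 2, with WS8-specific genes at 0.26 of their WS8 level above replicate 1, stood between the lines for these genes, and the log2 fold change of STAT1 went from 1.79 to 2.40 without it. Members of the AGR2 and LYPD3 family list were higher, with 7 of 9 called in both counts (median 1.13, adjusted p = 0.0021, and adjusted p = 0.58 with an estimated correlation). AGR2 was 4.62-fold higher (65.7 ± 11 against 14.2 ± 11 CPM, adjusted p = 0.011, log2 2.21, with 1.56 without MCF7 vehicle replicate 1 and 3.44 without replicate 2). Its call ended without WS8 vehicle replicate 2 (0.074). LYPD3 (log2 0.5, adjusted p = 0.027) lost its call without MCF7 vehicle replicate 1 (0.18) or WS8 vehicle replicate 2 (0.19). TFF1 was 2.47-fold higher (132 ± 15 against 53.6 ± 0.64 CPM, adjusted p = 0.0029), while GREB1 (80.2 ± 4.2 against 142 ± 34 CPM; 0.088), GRHL2 (217 ± 23 against 169 ± 31 CPM; 0.14), ESR1 (303 ± 25 against 407 ± 28 CPM; 0.05) and FOXA1 (384 ± 5.9 against 355 ± 64 CPM; 0.59) did not pass. PGR was 6.96-fold lower (1.4 ± 1.4 against 9.63 ± 3 CPM, adjusted p = 0.014, log2 −2.8, with −4.43 and −2.03 without WS8 vehicle replicates 1 and 2), and its call ended without MCF7 vehicle replicate 2 (0.054).

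Cell cycle genes were higher in WS8 than in MCF7, with 13 of 44 called higher and 0 lower (16 and 0 adjusted over the list alone, median 0.42, adjusted p = 3.1e-07, and adjusted p = 0.83 with an estimated correlation). The mitotic kinase gene AURKA was 1.86-fold higher. This list call ended without MCF7 vehicle replicate 2 (0.11) and without the 3 libraries that stood apart (0.05). Ribosomal protein genes were lower, 21 of 40 (31 adjusted over the list alone, median −0.35, adjusted p = 9e-10, and adjusted p = 0.58 with an estimated correlation). RPL4 was 2.11-fold lower. Mitochondrially encoded genes were called lower as a list with 0 members called in either count (median −0.57, adjusted p = 0.031, and adjusted p = 0.87 with an estimated correlation), until MCF7 vehicle replicate 1 (0.8) or WS8 vehicle replicate 1 (0.061) was left out. BCL2 was 5.12-fold lower (27.1 ± 9.7 against 138 ± 14 CPM, adjusted p = 0.0014). Among the lowest, GPER1, a G protein-coupled receptor that binds oestrogen, was 21.9-fold lower (14.5 ± 16 against 312 ± 63 CPM, with 25.4 and 3.48 CPM in WS8 vehicle replicates 1 and 2, log2 −4.45, with −6.47 and −3.63 without WS8 vehicle replicates 1 and 2). The secreted glycoprotein gene STC1 was 16.8-fold lower (7.62 ± 8.6 against 126 ± 29 CPM, log2 −4.07, with −6.3 and −3.21 without them). The 6 highest, MYEOV, EDARADD, VGLL1, PRSS16, VGLL3 and ADGRE2, were 7.21- to 27.2-fold higher with adjusted p between 0.011 and 0.046. All 6 calls ended without WS8 vehicle replicate 2 (0.054 to 0.18), and all but that of PRSS16 without WS8 vehicle replicate 1 (0.054 to 0.1). Those of MYEOV, VGLL1, VGLL3 and ADGRE2 also ended without MCF7 vehicle replicate 1 (0.053 to 0.24), and those of MYEOV and ADGRE2 without MCF7 vehicle replicate 2 (0.092 and 0.086). MYEOV, EDARADD, VGLL1, VGLL3 and ADGRE2 had log2 fold changes of 6.59, 9.29, 5.54, 6.65 and 3.75 without MCF7 vehicle replicate 2, in place of 4.77, 3.06, 2.97, 2.85 and 2.85, and PRSS16 had 5.75 without MCF7 vehicle replicate 1 in place of 2.92. The other 12 lists were not called (adjusted p of 0.12 or more), and median, mean and test differed in sign for the unfolded protein, hypoxia and non-epithelial lists. In all, 1744 genes were higher and 2076 lower. The 3820 calls compare with 1887 without MCF7 vehicle replicate 1, 2078 and 1194 without WS8 vehicle replicates 1 and 2, and 1744 in a fit of only these 4 libraries. Of 76 called named genes, 39 kept their call whichever library was left out.

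**Figure D3:**
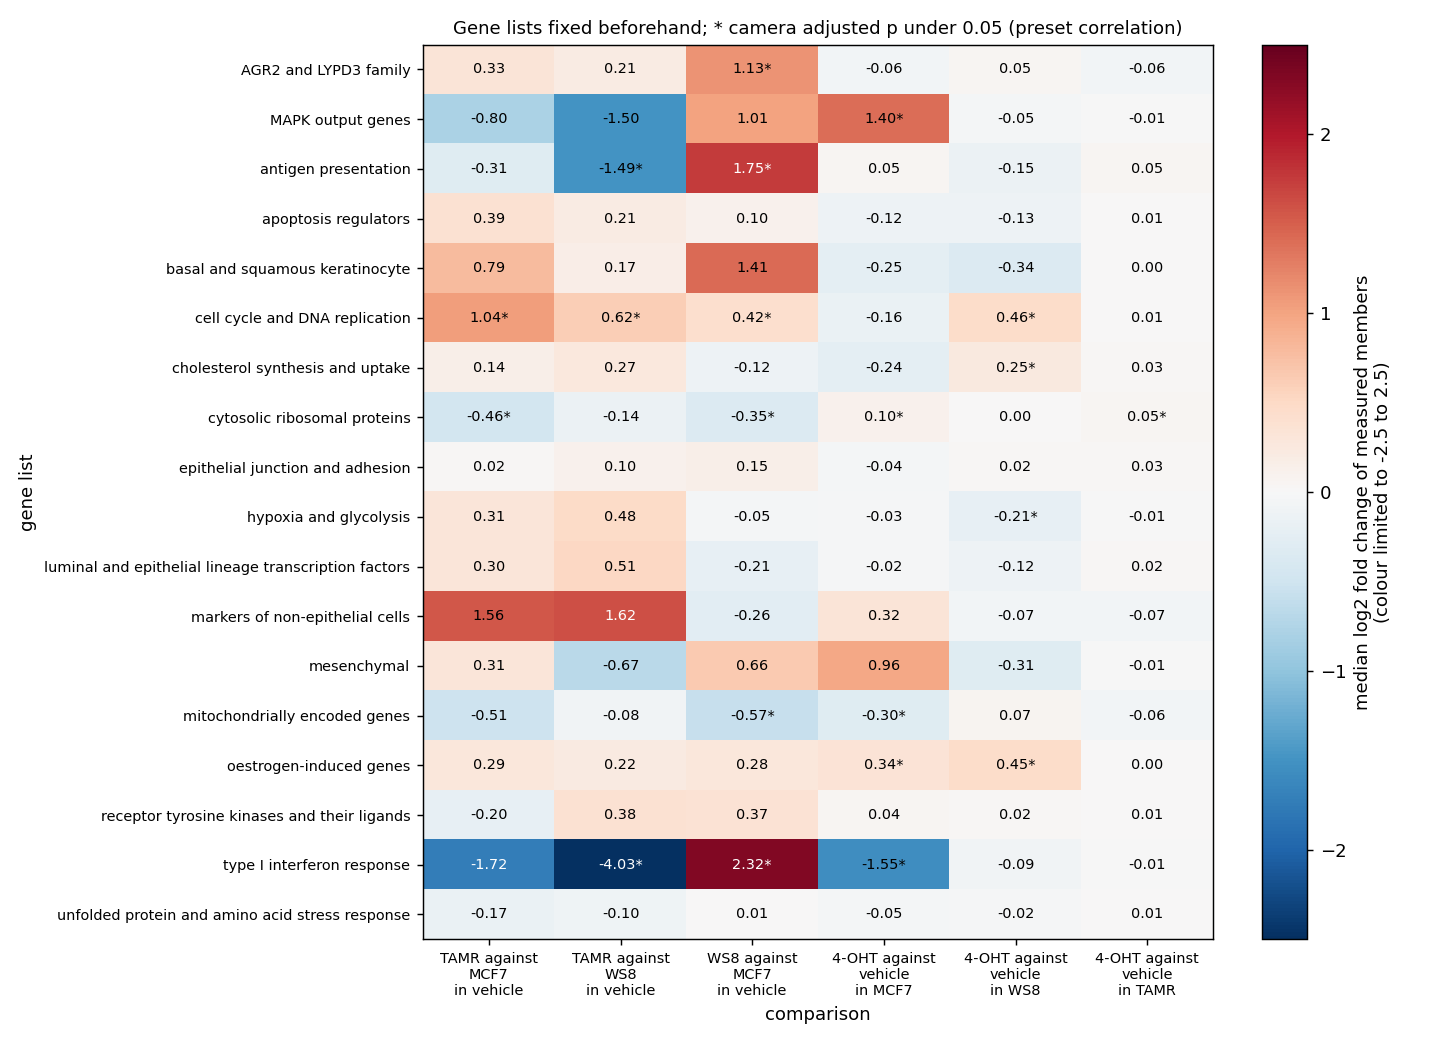
Median log2 fold change of the measured members of 18 gene lists (one per line) in 6 comparisons (columns), with colour limited to −2.5 to 2.5 and an asterisk where camera's adjusted p was under 0.05 with the preset correlation. Interferon genes stand at −4.03 in TAMR against WS8 and 2.32 in WS8 against MCF7, and no asterisk holds with an estimated correlation.

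With 4-OHT present, TAMR was compared with MCF7 to ask how the resistant line differs from its parent on drug. TFF1 was 21.7-fold higher in TAMR (497 ± 57 against 22.8 ± 5.8 CPM, adjusted p = 1.6e-06), LYPD3 2.68-fold (126 ± 7.8 against 47 ± 6.4 CPM, adjusted p = 5.3e-05) and GRHL2 1.65-fold (299 ± 12 against 182 ± 43 CPM, adjusted p = 0.006). PGR stood at 0.0387 ± 0.0065 against 22.1 ± 8 CPM, a ratio of 582 (interval 161 to 4810). GREB1 was 2.05-fold lower (26.8 ± 12 against 54.7 ± 3.3 CPM, adjusted p = 0.027). Its call ended without MCF7 4-OHT replicate 2 (0.073), without TAMR 4-OHT replicate 2 (0.18, log2 −0.62 in place of −1.04) and without the 3 libraries. AGR2 (116 ± 41 against 73.1 ± 3.1 CPM; 0.25), FOXA1 (351 ± 12 against 352 ± 68 CPM; 0.99) and ESR1 (311 ± 33 against 326 ± 61 CPM; 0.71) did not pass. SIGLEC6, a sialic acid-binding receptor gene at 47.2 ± 19 CPM in TAMR, had 0 counts in MCF7 and was at least 773-fold higher, and TNFSF15 was 1050-fold higher (log2 10.03, with 9.17 and 12.5 without MCF7 4-OHT replicates 1 and 2). Genes at 0 counts in TAMR were led by OXCT1 (64 ± 6.1 CPM in MCF7, at least 1120-fold lower), C5orf42 (at least 903-fold), SIGMAR1, a chaperone of the endoplasmic reticulum (at least 895-fold), TMTC1 (at least 734-fold), MEX3C (at least 615-fold) and SMAD4 (at least 607-fold). Cell cycle genes were higher, 38 of 44 (41 adjusted over the list alone, median 1.15, adjusted p = 7.5e-12, and adjusted p = 0.97 with an estimated correlation), with TOP2A 3.52-fold higher. Ribosomal protein genes were lower, 32 of 40 with 1 higher in both counts (median −0.52, adjusted p = 1.6e-08, and adjusted p = 0.97 with an estimated correlation). MAPK output genes had 10 of 19 lower and 0 higher in both counts (adjusted p = 0.13), with PHLDA1, a gene induced by growth factor signalling, 6.05-fold lower. MCF7 4-OHT replicate 2 held genes of this list such as DUSP6 at 67.3 CPM against 3.41 in replicate 1. The MAPK output list was called in the fit that kept replicate 2 as the only MCF7 4-OHT library. In all, 3445 genes were higher and 3704 lower, and the 16 uncalled lists had adjusted p of 0.13 or more. Median, mean and test differed in sign for the AGR2 and LYPD3 family, basal, receptor tyrosine kinase and non-epithelial lists.

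TAMR and WS8 were compared in 4-OHT for the same question against the sensitive derivative. TFF1 was 4.38-fold higher in TAMR (497 ± 57 against 113 ± 21 CPM, adjusted p = 4.8e-05), and LYPD3 was 1.5-fold higher (126 ± 7.8 against 84 ± 4.9 CPM, adjusted p = 0.0073), a call that ended without TAMR 4-OHT replicate 2 (0.061) or WS8 4-OHT replicate 1 (0.08). GREB1 stood at 26.8 ± 12 against 26.7 ± 0.92 CPM (adjusted p = 1), AGR2 at 116 ± 41 against 124 ± 6.3 CPM (0.88), GRHL2 at 299 ± 12 against 228 ± 6 CPM (0.079), FOXA1 at 351 ± 12 against 418 ± 27 CPM (0.19) and ESR1 at 311 ± 33 against 272 ± 9.3 CPM (0.29). PGR had a ratio of 30.3 in favour of WS8 (interval 7.95 to 258, adjusted p = 0.0066), a call that ended without TAMR 4-OHT replicate 2 (0.053). Interferon genes were again lower, 32 of 36 with 0 higher in both counts (median −3.69, adjusted p = 1.6e-10, and adjusted p = 0.89 with an estimated correlation). XAF1 and IFI44L, both induced by interferon, had 0 counts in TAMR and were at least 986-fold and at least 677-fold lower. Hypoxia and glycolysis genes were higher, 12 of 21 with 2 lower (13 and 2 adjusted over the list alone, median 0.72, adjusted p = 0.036, and adjusted p = 0.89 with an estimated correlation). The hexokinase gene HK2 was 2.94-fold higher, and this list call ended without TAMR 4-OHT replicate 2 (0.066). TNC (69.6 ± 1.7 CPM) and SIGLEC6 had 0 counts in WS8 and were at least 965-fold and at least 630-fold higher. FCGRT, the neonatal Fc receptor gene, had a ratio of 4350 (interval 781 to 172000; fitted log2 11.82, with 10.99 and 14.35 without WS8 4-OHT replicates 1 and 2). The 16 uncalled lists had adjusted p of 0.052 or more. Luminal, antigen presentation and MAPK output genes, each at 0.052, were called without some libraries, in fits with 1 library in a group. With members at 0 counts set to their bound, the list medians were the same to 2 decimals except for the mesenchymal (0.17 to 0.09) and basal lists (0.39 to 0.18) here, and the mesenchymal (−0.01 to 0.01) and interferon lists (−0.01 to 0) in the response of TAMR. In all, 3349 genes were higher and 3413 lower, 6762 together, against 4408 and 4486 without WS8 4-OHT replicates 1 and 2. Median, mean and test differed in sign for the mesenchymal and receptor tyrosine kinase lists.

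4-OHT was compared with vehicle in MCF7 to measure the drug response of the parental sensitive line. The spread was shared with groups whose replicates differed less, so these p-values may be too small. KRT13 rose 129-fold (27.8 ± 0.8 against 0.206 ± 0.17 CPM, n = 2, adjusted p = 1.8e-05), SDK2, a cell adhesion gene, 23.8-fold (65 ± 15 against 2.73 ± 0.64 CPM, adjusted p = 4.5e-05), and AMZ1, a metallopeptidase gene, 10.1-fold (38.8 ± 8.2 against 3.82 ± 1 CPM, adjusted p = 0.00049). The log2 fold change of KRT13 was 7.02, with 6.39 and 8.23 without MCF7 vehicle replicates 1 and 2. SERPINA1, the gene of the protease inhibitor alpha-1 antitrypsin, rose 18.7-fold (16.9 ± 0.85 against 0.899 ± 0.16 CPM, adjusted p = 0.0012), and SLC2A1 rose 2.72-fold (228 ± 18 against 83.9 ± 1 CPM, adjusted p = 0.00037). GATA4 went from 0 counts to 2.52 ± 1.3 CPM, at least 39.9-fold higher (adjusted p = 0.0098; fitted log2 8.96, and 8.33 without MCF7 4-OHT replicate 2). ATP2C2, a calcium pump gene, fell 2.66-fold (17.6 ± 2.7 against 46.8 ± 4 CPM, adjusted p = 0.0017). TFF1 fell 2.35-fold (22.8 ± 5.8 against 53.6 ± 0.64 CPM, adjusted p = 0.026). Its call ended without MCF7 4-OHT replicate 2 (0.12), MCF7 vehicle replicate 1 (0.08) or MCF7 vehicle replicate 2 (0.082) and without the 3 libraries. GREB1 (54.7 ± 3.3 against 142 ± 34 CPM; 0.15), PGR (22.1 ± 8 against 9.63 ± 3 CPM; 0.45) and AGR2 (73.1 ± 3.1 against 14.2 ± 11 CPM; 0.088) did not pass, and AGR2 passed without MCF7 vehicle replicate 2. GRHL2 (182 ± 43 against 169 ± 31 CPM; 0.87), FOXA1 (352 ± 68 against 355 ± 64 CPM; 0.99), ESR1 (326 ± 61 against 407 ± 28 CPM; 0.4) and LYPD3 (47 ± 6.4 against 53.5 ± 6.4 CPM; 0.65) did not pass either.

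Oestrogen-induced genes went both ways under 4-OHT in MCF7, with 7 of 38 higher and 1 lower (12 and 3 adjusted over the list alone, median 0.34, adjusted p = 4.8e-10, and adjusted p = 0.17 with an estimated correlation). SLC9A3R1, a scaffold protein gene, rose 3.04-fold (1610 ± 260 against 528 ± 10 CPM, adjusted p = 0.00069), RAPGEFL1 4.05-fold (40.2 ± 7 against 9.92 ± 1.3 CPM, adjusted p = 9e-04) and FKBP4, a co-chaperone of steroid receptors, 2.05-fold (576 ± 66 against 281 ± 9.8 CPM, adjusted p = 0.0011). MAPK output genes were called higher with 2 of 19 members higher and 0 lower (4 and 1 adjusted over the list alone, median 1.4, adjusted p = 0.00032, and adjusted p = 0.7 with an estimated correlation). PHLDA1 rose 2.68-fold and IER3, an early response gene, 2.78-fold. The list call ended without MCF7 4-OHT replicate 2 (0.86), the library with DUSP6 at 67.3 CPM, without MCF7 vehicle replicate 1 (0.11) and without all 3 libraries (0.061). Interferon genes were called lower with 1 of 36 members lower and 0 higher (11 and 0 adjusted over the list alone, median −1.55, adjusted p = 4.5e-09, and adjusted p = 0.78 with an estimated correlation). IRF9, the member called, stood at 10.3 ± 0.23 against 28.3 ± 9.2 CPM (adjusted p = 0.025). Its call ended without MCF7 4-OHT replicate 2 (0.12), MCF7 vehicle replicate 2 (0.067), which held WS8-specific genes, or all 3 libraries. Mitochondrially encoded genes (median −0.3, adjusted p = 0.043, and adjusted p = 0.78 with an estimated correlation) and ribosomal protein genes (median 0.1, adjusted p = 0.00069, and adjusted p = 0.78 with an estimated correlation) were called with 0 members called in either count. The mitochondrial call ended without MCF7 4-OHT replicate 1 (0.3) and turned to higher, uncalled, without MCF7 vehicle replicate 1 (0.11), and the ribosomal call without MCF7 4-OHT replicate 1 (0.21), MCF7 vehicle replicate 2 (0.072) or all 3 libraries (0.29). The other 13 lists were not called (adjusted p of 0.072 or more), and median, mean and test differed in sign for the AGR2 and LYPD3 family, basal, hypoxia and apoptosis lists. The direction of the cell cycle list depended on the MCF7 vehicle library kept, with an adjusted p of 1.6e-16 for lower without vehicle replicate 2 and 1.3e-07 for higher without vehicle replicate 1. In all, 71 genes rose and 37 fell, while 52 rose and 105 fell without MCF7 vehicle replicate 1. The 108 calls compare with 306 without the 3 libraries, which leaves 1 MCF7 library per group, 1609 without MCF7 4-OHT replicate 1, 73 without MCF7 4-OHT replicate 2, 481 by DESeq2 and 0 in a fit of only the 4 MCF7 libraries. Of 24 called named genes, 14 kept their call whichever library was left out.

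The same comparison in WS8 measured the response of the sensitive derivative. KRT13 rose 46.4-fold (22.6 ± 0.39 against 0.476 ± 0.1 CPM, adjusted p = 5.1e-05) and RAPGEFL1 5.39-fold (77 ± 5.9 against 14.3 ± 2.2 CPM, adjusted p = 0.00059). KCNF1, a potassium channel subunit gene, rose 7.89-fold (24.9 ± 1.7 against 3.15 ± 0.16 CPM, adjusted p = 0.0017) and ARHGEF28, a Rho exchange factor gene, 4.11-fold (13.9 ± 0.51 against 3.38 ± 0.21 CPM, adjusted p = 0.0017). AMZ1 rose 4.94-fold (54.9 ± 0.91 against 11.1 ± 2.5 CPM, adjusted p = 0.004). CLEC3A, a lectin gene and the 1 gene that fell, decreased 1.74-fold (22.5 ± 1 against 39.1 ± 5.5 CPM, adjusted p = 0.049). The calls of KCNF1 and ARHGEF28 ended without WS8 vehicle replicate 1 (0.094 and 0.083), and that of AMZ1 without WS8 vehicle replicate 1 (0.11), WS8 4-OHT replicate 1 (0.071) or WS8 4-OHT replicate 2 (0.057). CLEC3A lost its call without WS8 4-OHT replicate 1 (0.72), WS8 4-OHT replicate 2 (0.43), WS8 vehicle replicate 1 (0.11) or WS8 vehicle replicate 2 (0.13). Oestrogen-induced genes were called higher, 5 of 38 with 0 lower (14 and 1 adjusted over the list alone, median 0.45, adjusted p = 1.8e-13, and adjusted p = 0.077 with an estimated correlation). Cell cycle genes (8 and 0 adjusted over the list alone, median 0.46, adjusted p = 2.3e-24, and adjusted p = 0.42 with an estimated correlation) and cholesterol genes (0 and 0, median 0.25, adjusted p = 5.7e-08, and adjusted p = 0.59 with an estimated correlation) were called as lists with 0 members called over all genes. Hypoxia genes were called lower as a list (median −0.21, adjusted p = 0.039, and adjusted p = 1 with an estimated correlation) while their 1 called member in both counts, SLC2A1, was 1.82-fold higher. That list call ended without WS8 4-OHT replicate 2 (0.099), WS8 vehicle replicate 1 (0.82) or the 3 libraries (0.74). The call of SLC2A1 ended without WS8 4-OHT replicate 1 (0.2), WS8 4-OHT replicate 2 (0.1), WS8 vehicle replicate 1 (0.14) or WS8 vehicle replicate 2 (0.066) and without the 3 libraries. GREB1 (26.7 ± 0.92 against 80.2 ± 4.2 CPM; 0.24), AGR2 (124 ± 6.3 against 65.7 ± 11 CPM; 0.71), TFF1 (113 ± 21 against 132 ± 15 CPM; 0.86), GRHL2 (228 ± 6 against 217 ± 23 CPM; 0.96), FOXA1 (0.9), ESR1 (0.86), LYPD3 (0.87) and PGR (0.96) did not pass. The other 14 lists were not called (adjusted p of 0.14 or more), and median, mean and test differed in sign for the luminal, junction, receptor tyrosine kinase, MAPK and unfolded protein lists. In all, 22 genes rose and 1 fell, while 15 rose and 32 fell without WS8 vehicle replicate 2 and DESeq2 called 75 higher and 48 lower. The 23 calls compare with 5 and 7 without WS8 4-OHT replicates 1 and 2, 2 and 47 without WS8 vehicle replicates 1 and 2, 123 by DESeq2 and 297 in a fit of only the 4 WS8 libraries. Of 13 called named genes, only KRT13 and RAPGEFL1 kept their call whichever library was left out.

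In TAMR, 4-OHT against vehicle measured the response of the resistant line. No gene passed: edgeR called 0 genes, with 59 at an unadjusted p under 0.05 and a smallest adjusted p of 1, and DESeq2 called 4. Evenly spread p-values over 14072 unchanged genes would put more than 59 under 0.05, so the test was conservative for this line. It used a spread shared by all groups, whose common coefficient of variation was 0.19, and 0.098 without the 3 libraries that stood apart. The 0 calls are therefore not a measure of no response. KRT13 stood at 78.5 ± 10 CPM with 4-OHT and 78.4 ± 13 CPM with vehicle, TFF1 at 497 ± 57 and 506 ± 82, GRHL2 at 299 ± 12 and 301 ± 16, AGR2 at 116 ± 41 and 121 ± 35, and GREB1 at 26.8 ± 12 and 18.6 ± 7.9 CPM. LYPD3 (126 ± 7.8 and 126 ± 15 CPM), FOXA1 (351 ± 12 and 356 ± 14 CPM) and ESR1 (311 ± 33 and 309 ± 31 CPM) had adjusted p of 1, and PGR was under the floor of 3 counts in both groups. Ribosomal protein genes were called as a list with 0 members called in either count (median 0.05, adjusted p = 1.1e-05, and adjusted p = 1 with an estimated correlation), a call whose direction turned without TAMR 4-OHT replicate 2 (0.22) and TAMR vehicle replicate 1 (0.42). The other 17 lists had 0 members called and adjusted p of 0.81 or more, and median, mean and test differed in sign for the receptor tyrosine kinase, hypoxia, apoptosis and non-epithelial lists.

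Whether the response differed between lines was tested as the difference of responses. The response of KRT13 was smaller in TAMR than in MCF7 (log2 difference −7.01, SE 0.36, adjusted p = 9.6e-05), as were those of SDK2 (−4.42, SE 0.3, adjusted p = 0.00059) and AMZ1 (−3.31, SE 0.31, adjusted p = 0.0056). SLC2A1 differed by −1.44 (SE 0.14, adjusted p = 0.0056), RAPGEFL1 by −2.09 (SE 0.22, adjusted p = 0.0089) and SLC9A3R1 by −1.59 (SE 0.17, adjusted p = 0.0089). KRT13 ran from −8.23 without MCF7 vehicle replicate 2 to −6.39 without MCF7 vehicle replicate 1. The call of AMZ1 ended without TAMR 4-OHT replicate 1 (0.069), TAMR 4-OHT replicate 2 (0.056) or TAMR vehicle replicate 2 (0.051), and that of SLC2A1 without TAMR 4-OHT replicate 1 (0.069) or TAMR vehicle replicate 2 (0.051). The calls of RAPGEFL1 and SLC9A3R1 ended without TAMR 4-OHT replicate 1 (0.093 and 0.069), TAMR 4-OHT replicate 2 (0.1 and 0.098), TAMR vehicle replicate 1 (0.067 and 0.074) or TAMR vehicle replicate 2 (0.051 and 0.066). In all, 25 genes had a lower and 3 a higher response in TAMR than in MCF7, while 16 were lower and 18 higher without MCF7 vehicle replicate 1, with 16 of the 28 calls shared. The 28 calls compare with 81 without the 3 libraries, 107 by DESeq2 and 8 in a fit of only these groups. Leaving out a library gave 435 (MCF7 4-OHT replicate 1), 44 (MCF7 vehicle replicate 2), 3 and 4 (TAMR 4-OHT replicates 1 and 2) and 9 and 3 (TAMR vehicle replicates 1 and 2). Of the 3, CLEC3A and ATP2C2 fell under the rule for named genes and PALM2-AKAP2, a read-through gene whose counts are uncertain, was added after the values were seen (log2 12.03, adjusted p = 0.027). The calls of CLEC3A and ATP2C2 ended without each of the 4 TAMR libraries (0.069 to 0.12 and 0.12 to 0.28), and that of ATP2C2 also without MCF7 4-OHT replicate 2 (0.079), MCF7 vehicle replicate 1 (0.053) or MCF7 vehicle replicate 2 (0.094). Oestrogen-induced genes had 5 members lower and 0 higher (9 and 3 adjusted over the list alone, median −0.3, adjusted p = 1.1e-08, and adjusted p = 0.23 with an estimated correlation), a call that ended without MCF7 4-OHT replicate 1 (0.055). None of the 8 genes of interest passed, TFF1 differing by 1.21 (adjusted p = 0.28), GREB1 by 1.89 (0.37) and AGR2 by −2.42 (0.5), which passed without MCF7 vehicle replicate 2. GREB1 passed with a replicate block within each line.

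**Figure D4:**
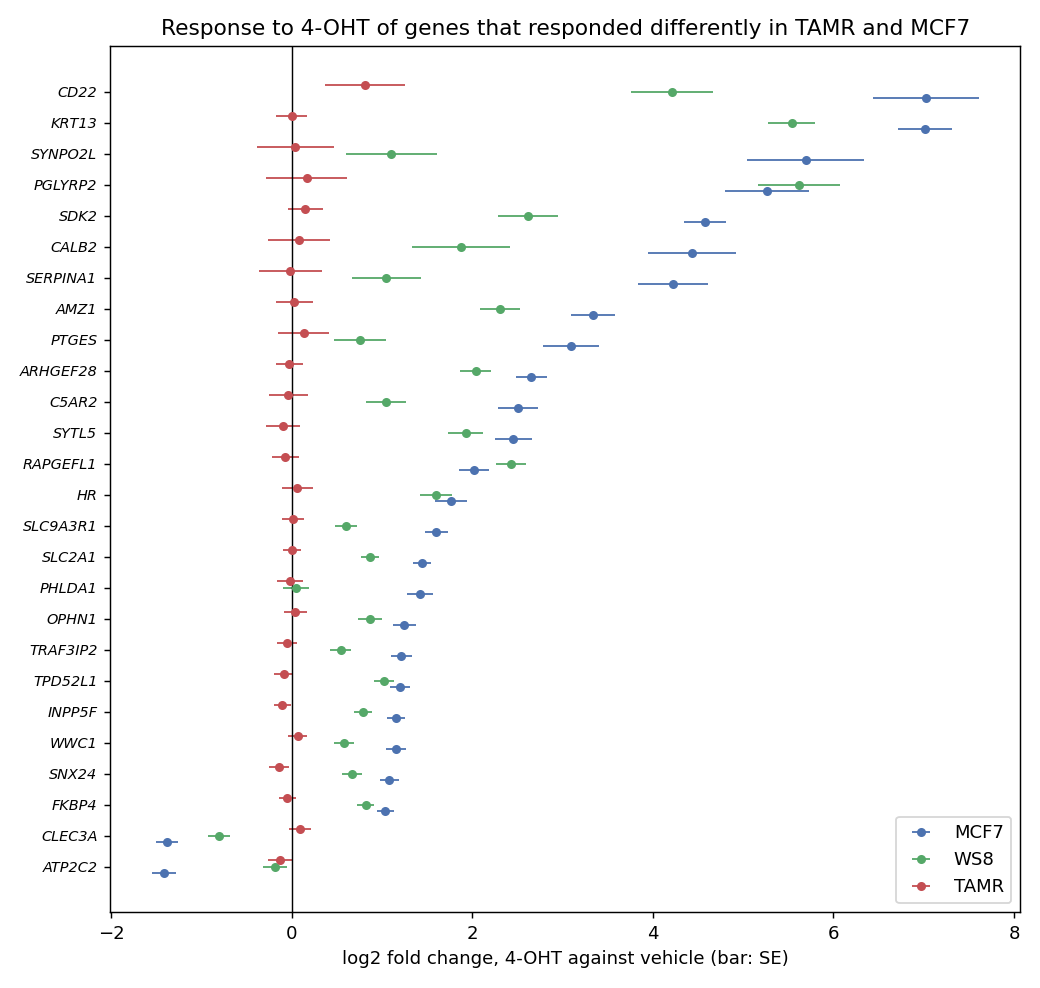
Log2 fold change of 4-OHT against vehicle (bars, SE) in MCF7, WS8 and TAMR for 26 of the 28 genes whose response differed between TAMR and MCF7, leaving out PALM2-AKAP2 and GATA4, whose counts are uncertain or 0 in a group. KRT13 lies at 7.02 in MCF7 and 5.54 in WS8, and at 0 in TAMR, where CD22 lies highest at 0.82.

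Between TAMR and WS8, the response of KRT13 differed by −5.54 (SE 0.32, adjusted p = 3e-04), RAPGEFL1 by −2.5 (SE 0.22, adjusted p = 0.0069), KCNF1 by −3.1 (SE 0.33, adjusted p = 0.023) and ARHGEF28 by −2.06 (SE 0.23, adjusted p = 0.023). The fifth gene, PGLYRP2 (−5.45, adjusted p = 0.03), fell outside the rule for named genes and was added after its values were seen. KRT13 alone kept its call whichever library was left out. The calls of KCNF1 and ARHGEF28 ended without each of the 8 libraries (adjusted p of 0.056 to 0.28 and 0.07 to 0.27), and that of RAPGEFL1 without each but TAMR vehicle replicate 2 and WS8 vehicle replicate 2 (0.056 to 0.11). The 5 calls were all lower. There were 9 without WS8 vehicle replicate 2, of which 7 were higher, 2 lower and 2 shared with the 5, 2 without TAMR vehicle replicate 2 and 1 without any other, with 30 by DESeq2, 17 in a fit of only these groups, 9 with upper-quartile factors and 8 without the 3 libraries. Oestrogen-induced genes had 1 member lower and 0 higher (7 and 1 adjusted over the list alone, median −0.46, adjusted p = 4.8e-11, and adjusted p = 0.13 with an estimated correlation). Cell cycle genes (median −0.47, adjusted p = 2e-20, and adjusted p = 0.51 with an estimated correlation) and cholesterol genes (median −0.2, adjusted p = 2.3e-05, and adjusted p = 0.94 with an estimated correlation) had 0 members called in either count. Between the sensitive lines, edgeR called 0 genes with a different response, with 1036 at an unadjusted p under 0.05 and a smallest adjusted p of 0.485. DESeq2 called 97, and edgeR 35 without the 3 libraries, 462 and 59 without MCF7 4-OHT replicate 1 and MCF7 vehicle replicate 2, 10 without MCF7 vehicle replicate 1 and 5 without WS8 vehicle replicate 2. Median, mean and test differed in sign for the AGR2 and LYPD3 family, hypoxia and apoptosis lists between TAMR and MCF7, for the receptor tyrosine kinase, MAPK and unfolded protein lists between TAMR and WS8, and for the luminal, AGR2 and LYPD3 family, oestrogen-induced, junction and apoptosis lists between WS8 and MCF7.

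The genes that 4-OHT changed in MCF7 were read in the other lines. Of the 71 raised in MCF7, 65 were higher with 4-OHT in WS8 (20 called, median log2 0.68, camera p = 0.00043 with an estimated correlation) and 35 in TAMR (0 called, median 0). Of the 37 lowered, 35 were lower in WS8 (1 called, median −0.24) and 15 in TAMR (0 called, median 0.01). The difference of responses between TAMR and WS8 had a median of −0.81 over the 71 genes (camera p = 0.00045 with an estimated correlation). MCF7 and WS8 shared 21 called genes in the same direction, against 0.11 for independent lists, and these lines share no libraries. Both lists came from 1 fit with the same spread per gene, so 0.11 is only a rough chance value. Already in vehicle, 59 of the 71 were higher in TAMR than in WS8 (50 called, median 1.03, camera p = 0.033 with an estimated correlation) and 28 of the 37 were lower (25 called, median −0.71, p = 0.044). Over all 14072 genes, 3364 were called higher and 3316 lower in that comparison. SLC2A1 stood at 253 ± 19 CPM in TAMR in vehicle, 113 ± 5.4 CPM in WS8 in vehicle and 206 ± 12 CPM in WS8 with 4-OHT, against 228 ± 18 CPM in MCF7 with 4-OHT. Other raised genes stood below the treated level of MCF7 in TAMR in vehicle, such as SLC9A3R1 (494 ± 19 against 1610 ± 260 CPM), SDK2 (12.4 ± 0.6 against 65 ± 15 CPM), PHLDA1 (29.4 ± 1.9 against 176 ± 25 CPM) and KIF12 (13 ± 5.2 against 36.8 ± 9.6 CPM). Of the 25 genes with a smaller response in TAMR than in MCF7, 16 stood at 1/1.5 of the MCF7 4-OHT level or above in TAMR in vehicle and 9 below, and 21 did so for the WS8 4-OHT level. With the sets chosen instead without the 3 libraries, from 1 MCF7 library per group, 97 of 175 raised genes were higher in TAMR than in WS8 in vehicle (75 called, median 0.17) and 68 of 131 lowered genes were lower (58 called, median −0.17). Of these larger sets, 127 and 68 moved the same way in WS8 (18 and 0 called, medians 0.26 and −0.01), and 91 and 56 in TAMR (0 called, medians 0 and 0.01).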

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

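The tests of the 3 libraries that stood apart and of the vehicle level of TAMR were chosen after the results were seen, and the test of a ceiling was written before. The results in this part were singled out because the response to 4-OHT differed between cell lines in a test of the difference itself. Between TAMR and MCF7, 28 genes differed. Their log2 differences were −7.01 for KRT13, −4.42 for SDK2, −4.23 for SERPINA1 (adjusted p = 0.013), −3.31 for AMZ1, −2.96 for PTGES, a prostaglandin synthase gene (adjusted p = 0.029), −2.09 for RAPGEFL1, −1.59 for SLC9A3R1, −1.44 for SLC2A1, −1.44 for PHLDA1 (adjusted p = 0.029), −1.29 for TPD52L1 and −1.08 for FKBP4 (adjusted p = 0.013 for both). GATA4 had a fitted difference of −8.74 (adjusted p = 0.044), which rests on 0 counts in MCF7 in vehicle and has no fold. The differences of CLEC3A and ATP2C2 were positive, 1.47 (adjusted p = 0.013) and 1.29 (adjusted p = 0.038). Between TAMR and WS8, 5 genes differed, with −5.54 for KRT13, −3.1 for KCNF1, −2.5 for RAPGEFL1 and −2.06 for ARHGEF28, and PGLYRP2 outside the rule for named genes. Of the 14 named genes between TAMR and MCF7 only KRT13 and SDK2, and of the 4 between TAMR and WS8 only KRT13, kept the call whichever library was left out. The calls of GATA4 and SERPINA1 ended at adjusted p up to 0.28 and 0.11.

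Gene lists whose response differed were called with the preset correlation only, at camera adjusted p of 1.1e-08 (oestrogen-induced), 0.0037 (MAPK output), 0.036 (cholesterol) and 1.3e-05 (interferon) between TAMR and MCF7. With an estimated correlation the adjusted p was 0.23 for the oestrogen-induced list and 0.81 for the other 3. The medians were −0.3, −1.44, 0.29 and 1.4, and 5, 1, 0 and 0 members were called. Between TAMR and WS8 the adjusted p was 4.8e-11 (oestrogen-induced), 2e-20 (cell cycle) and 2.3e-05 (cholesterol), and 0.13, 0.51 and 0.94 with an estimated correlation. Between WS8 and MCF7 it was 7.7e-18 (cell cycle, median 0.62), 0.0058 (MAPK output, −1.35), 5.5e-09 (cholesterol, 0.46), 2.3e-09 (interferon, 1.47), 0.019 (hypoxia, −0.23), 0.027 (mitochondrially encoded, 0.37) and 0.0017 (ribosomal proteins, −0.11), with 0 members called over all genes. With an estimated correlation these were 0.67 for the cell cycle, cholesterol and interferon lists and 0.72 for the other 4. Adjusted over the list alone, 9 oestrogen-induced and 2 MAPK output genes were lower, and 3 oestrogen-induced and 2 interferon genes higher, between TAMR and MCF7. Between WS8 and MCF7, 7 cell cycle genes and 1 interferon gene were higher, and 1 MAPK output gene and 1 hypoxia gene lower. MCF7 4-OHT replicate 2 held MAPK output genes above replicate 1 (SPRY4 108 against 0.853 CPM, ETV5 73.6 against 0.349 CPM), and MCF7 vehicle replicate 2 held interferon genes (XAF1 17.1 against 0.0436 CPM). The MAPK output call between TAMR and MCF7 ended without MCF7 4-OHT replicate 2 (0.67) or MCF7 vehicle replicate 1 (0.19), and the interferon call without MCF7 vehicle replicate 2 (0.12) or MCF7 4-OHT replicate 1 (0.097). The cholesterol call between them ended without MCF7 4-OHT replicate 2 (0.56), TAMR 4-OHT replicate 1 (0.082) or TAMR vehicle replicate 2 (0.15), and turned without MCF7 vehicle replicate 1. Between WS8 and MCF7, the calls of the MAPK output, interferon, hypoxia, mitochondrially encoded and ribosomal lists each ended without at least 1 library, at adjusted p of up to 0.97, 0.1, 0.58, 0.35 and 0.19.

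That 4-OHT changed genes in MCF7 and not in TAMR was weighed against RNA of other cells in the 3 libraries that stood apart. Without those libraries 25 of the 28 genes kept their call and direction. These calls are no independent support, since the 28 genes were chosen with the remaining libraries included. That fit also compares 1 MCF7 library with 1, takes their spread from other groups and has a lower common coefficient of variation (0.098 against 0.19). The differences themselves went from −7.01 to −8.26 for KRT13, from −1.44 to −1.1 for PHLDA1 and from −5.65 to −8.82 for SYNPO2L. They were thus present without the 3 libraries, within the limits of 1 library per MCF7 group. Their size was selected along with the calls, so it is no independent evidence against such RNA as a cause. Without MCF7 4-OHT replicate 2 alone 26 of the 28 calls were shared, without MCF7 vehicle replicate 2 alone 22 and without MCF7 vehicle replicate 1 alone 16. Whether TAMR in vehicle already sits at the treated level stays open, since 16 of the 25 genes with a smaller response in TAMR than in MCF7 stood in TAMR in vehicle at 1/1.5 of their MCF7 4-OHT level or above and 9 stood below, such as SDK2 (12.4 against 65 CPM), SERPINA1 (2.28 against 16.9 CPM) and PHLDA1 (29.4 against 176 CPM, and 65.6 CPM in MCF7 in vehicle). Against WS8 in vehicle 23 of the 25 were higher in TAMR (median log2 0.99 without the 3 libraries), but they were selected with the same TAMR vehicle libraries, and of 175 raised genes chosen without the 3 libraries, a set that rests on 1 MCF7 library per group, 97 were higher, at a median of 0.17. A ceiling reached gene by gene is argued against by the 12 MCF7-raised genes that were not higher in TAMR than in WS8 in vehicle. Their median log2 response in TAMR was −0.02, against 0.53 in WS8 and 1.15 in MCF7. The bootstrap interval of −0.07 to 0.06 resampled these genes within the same libraries, so it leaves out the spread between libraries. A stable state of the line, drug left from its culture and a lost drug response were not tested.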

How the results depend on the processing

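The fits without the 3 libraries that stood apart and with the deposited per-gene factors as offsets were tests chosen after the data were seen. No comparison count changed its split between higher and lower by more than 10 percentage points under upper-quartile or RLE scaling, and no named gene reversed under any setting. A log2 minimum of 1 gave 3094 calls for TAMR against MCF7 and 2700 for TAMR against WS8 in vehicle, 1049 for WS8 against MCF7, 3116 and 2742 for TAMR against MCF7 and WS8 in 4-OHT, 71 for the MCF7 response and 1849 against both lines, as its construction lowers counts. An adjusted p under 0.01 likewise gave 1545 for WS8 against MCF7, 35 and 13 for the responses of MCF7 and WS8, 9 and 2 for the response of TAMR minus those of MCF7 and WS8, and 3018 against both lines. For the changes that follow the cause was not tested. DESeq2 gave 481, 123 and 4 calls for the responses of MCF7, WS8 and TAMR, and 107, 30 and 97 for the differences TAMR minus MCF7, TAMR minus WS8 and WS8 minus MCF7. With only the groups compared there were 1744 calls for WS8 against MCF7, 0 and 297 for the responses of MCF7 and WS8, and 8 and 17 for TAMR minus MCF7 and TAMR minus WS8. Upper-quartile factors gave 9 for TAMR minus WS8. Without the 3 libraries there were 306 for the MCF7 response, 81, 8 and 35 for the differences in the order above. Leave-one-out ranges were 1194 to 3810 for WS8 against MCF7, 4408 to 4739 for TAMR against WS8 in 4-OHT, 73 to 1609 and 2 to 47 for the responses of MCF7 and WS8, and 3 to 435, 1 to 9 and 0 to 462 for the differences. The replicate numbers were not taken as pairs, since the differences between replicates 2 and 1 under both treatments correlated at 0.18 in MCF7 and 0.34 in TAMR but −0.01 in WS8, and the labels name no shared day. In TAMR, libraries with the same number correlated best (0.993 against 0.989 to 0.99), a hint of pairing in that line. A replicate block shared by all lines gave 7379, 6846 and 4063 calls for the vehicle comparisons of TAMR with MCF7, TAMR with WS8 and WS8 with MCF7, 7255 and 6916 for TAMR against MCF7 and WS8 in 4-OHT, and 137, 20 and 0 for the responses of MCF7, WS8 and TAMR. It gave 26, 7 and 0 for the differences and 4826 against both lines, and ended the calls of mitochondrially encoded genes in WS8 against MCF7 (0.053) and in the MCF7 response (0.076). It also ended the calls of GATA4, PHLDA1 and ATP2C2 in TAMR minus MCF7, CLEC3A in the WS8 response, GRHL2 in TAMR against WS8 in vehicle and HLA-B in TAMR against MCF7 in 4-OHT. It added calls of ESR1 in WS8 against MCF7, AGR2 in the MCF7 response, the interferon list in TAMR against MCF7 in vehicle (0.025) and the antigen presentation list in TAMR against WS8 in 4-OHT (0.038) and in WS8 minus MCF7 (0.041). A replicate block within each line gave 237 for the MCF7 response, 3 for TAMR minus WS8, 2 for WS8 minus MCF7 and 39 for TAMR minus MCF7, sharing 14 of the 28 calls and without those of GATA4, SERPINA1, PHLDA1 and ATP2C2. It also lacked the calls of RAPGEFL1 and ARHGEF28 in TAMR minus WS8, GRHL2 and RBFOX3 in TAMR against WS8 and MT-CO1, MT-ND2 and MT-ND4L in TAMR against MCF7 in vehicle, DDR1 in the MCF7 response and CLEC3A, PDZK1 and XBP1 in the WS8 response. It added ESR1 in WS8 against MCF7, AGR2 in the MCF7 response, and GREB1 in WS8 against MCF7, in the responses of MCF7 and WS8 and in TAMR minus MCF7 and TAMR minus WS8. An estimated correlation ended all 39 list calls, and the other 159 list results stayed uncalled. Of the 159 list results not called, 49 were called without at least 1 library. Some list results reversed when 1 library was left out, with camera adjusted p as follows. Without MCF7 4-OHT replicate 2 this was MAPK output in WS8 minus MCF7 (0.97, range 1.8e-08 to 0.97). Without MCF7 vehicle replicate 1 these were cholesterol in WS8 against MCF7 (0.038, to 0.64), cell cycle in the MCF7 response (1.3e-07, range 1.6e-16 to 0.89), mitochondrially encoded genes in the MCF7 response (0.11, range 3.7e-08 to 0.3), cell cycle (4.7e-07, range 1.1e-17 to 0.86) and cholesterol (0.36, range 6.4e-09 to 0.56) in TAMR minus MCF7, and mitochondrially encoded genes in WS8 minus MCF7 (0.35, range 6e-08 to 0.35). In the TAMR response, basal genes reversed without TAMR 4-OHT replicate 1 (0.018) and TAMR vehicle replicate 2 (0.0056), range 0.0035 to 0.031, and hypoxia genes without TAMR 4-OHT replicate 2 (0.031) and TAMR vehicle replicate 1 (0.026), range 0.0081 to 0.031. Ribosomal protein genes reversed there without TAMR 4-OHT replicate 2 (0.22) and TAMR vehicle replicate 1 (0.42), range 5.8e-18 to 0.42, and mitochondrially encoded genes without TAMR vehicle replicate 2 (0.00054), range 5e-07 to 0.97. Depth limits what 0 counts mean, since 3 counts in a library were 0.102 to 0.152 CPM.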

Other observations

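The comparisons of cell lines in 4-OHT were planned, and the tests of the 3 libraries and of the chromosome 18 run were chosen after the results were seen. XBP1 stood at 2380 ± 63 CPM in TAMR, 244 ± 14 in MCF7 and 641 ± 14 in WS8, each with 4-OHT and n = 2, and TFF3 stood at 384 ± 70 in TAMR and 3.77 ± 0.51 CPM in MCF7. KRT13 with 4-OHT was still 2.83-fold higher in TAMR than in MCF7 (78.5 ± 10 against 27.8 ± 0.8 CPM) and 3.47-fold higher than in WS8 (22.6 ± 0.39 CPM). ERBB2, a growth factor receptor gene, was 2.66-fold higher in TAMR than in WS8 with 4-OHT (522 ± 22 against 197 ± 3.2 CPM). NDRG1, a gene induced by low oxygen, was 27.8-fold higher (481 ± 180 against 17.3 ± 0.35 CPM).

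In MCF7 4-OHT replicate 2, 636 genes stood above 1 CPM and over 5 times any other library, and they held 17 of 18 melanocyte-lineage genes against 0.87 expected by chance, with VIM at 403 against 0.504 CPM in replicate 1, so the values fit melanocyte-lineage RNA in that library. Of 647 genes over 5 times every library but MCF7 4-OHT replicate 1, 40 were at least 2-fold higher in that replicate than in MCF7 vehicle replicate 1, which argues against a response to 4-OHT as the source of most of them. In MCF7 vehicle replicate 2, 29 WS8-specific genes outside the interferon and antigen lists stood at a median share of 0.26 of the WS8 level above replicate 1, and 19 in the lists at 0.25, which fits RNA of WS8 cells. WS8 vehicle replicate 1 held the 41 genes high in TAMR at 0.059 of their TAMR level, against 0.00071 in replicate 2. It held the 3 genes high in MCF7 at 0.11 of their MCF7 level, against 0.006. Single genes varied: TNFSF15, at 444 and 506 CPM in TAMR vehicle, stood at 0.268 CPM there and 0.257 in replicate 2. VIM, at 12.9 and 17 CPM in TAMR vehicle, stood at 3.84 against 0.22 CPM. The keratin genes KRT5 and KRT6C stood at 6.21 and 1.92 CPM there, and at 0 in TAMR vehicle and in replicate 2. The source of these transcripts was not tested. Whether such RNA entered in culture, at extraction or as shared reads between libraries was not tested.

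The run of 7 neighbouring chromosome 18 genes without expression in TAMR fits loss of a segment, since the longest run among 10000 shuffles of the 35 genes was 3 (permutation p = 1e-04, the smallest possible). Silencing of the region with the DNA kept cannot be told apart from it, as the highest count of a run gene in a TAMR library was 1 and no DNA was analysed here. Copies that the parental line or WS8 may carry or lack were not analysed here. Chromosome 5 held 5 of the 35 genes, SEMA5A, C5orf42, OXCT1, CCL28 and ANKRD34B.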
